A study of Drosophila melanogaster with 12 samples.

How the data were processed

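ATAC-seq libraries from labelled fat body and labelled gut of adult female flies were compared, with 3 control and 3 switched libraries per tissue. Per the labels' protocols, flies were reared on 10% yeast and 5% sucrose, mated for 48 h and separated from males, nuclei of dissected tissue were tagmented with Tn5 and libraries were amplified by PCR. The authors deposited raw read counts per region, in 1 table for each tissue, and the sheet that accompanies them calls the values read counts. Per the submitters' processing notes the tools were FastQC, Trimmomatic, MACS2, featureCounts and DESeq2, with no versions or roles; the column layout of both tables is that of featureCounts. The aligner, the genome build, whether peaks were called per library or on pooled libraries, the removal of duplicate or mitochondrial reads and any shift of reads to the Tn5 cut site are not given in the sources used here. Duplicates that stay in the counts would raise the spread between libraries, and mitochondrial regions were part of the deposited counts.

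Groups and replicate numbers came from the sample titles, and columns were matched to samples by name. Every pair of libraries in a table differed beyond counting noise, so none was merged as a repeat deposit; this check does not tell separate animals from libraries amplified again from 1 sample. The counts were checked as whole numbers with different totals per library.

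Coordinates are those of the deposited regions. The build is not named, and it was settled from the data: regions of the table labelled gut fell at gene ends of Drosophila melanogaster Release 6 in 44.5% of cases, against 18.9% to 21.6% after moving them by 5 or 10 kb, and 411 regions of the table labelled fat body overlapped the other table against 15 to 21 after such moves. Gene assignments rest on this match. A region was assigned to a protein-coding gene it overlaps, or otherwise to the nearest within 1000 bp, from a table of 13951 genes of Release 6 that holds gene spans and no exons or strands. Exons, introns and transcription starts could therefore not be told, and a gene end, meaning either end within 500 bp of the region's midpoint, stood in for the promoter. Motif shares were planned and not run, since no genome sequence was used here.

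Tests were fixed before the data were examined. Region counts were fitted per tissue with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, quasi-likelihood F test of switched against control), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was its size over the square root of F. The filter kept 1674 of 3447 and 1944 of 2906 regions, and the common dispersion was 1.40 and 1.38. Normalised counts (CPM) used the TMM factors. DESeq2 1.42.0 was the alternative test, and its adjusted p stayed undefined for 1395 regions labelled fat body and 10 labelled gut. Where a group had 0 counts in all libraries, the fold is a lower bound with 3 counts over that group as the floor. This bound covers counting error only and not the spread between libraries. The interaction of tissue and induction was fitted with edgeR on merged overlapping regions. Scaling moved the median log2 fold change of the same regions labelled fat body from 0.25 with TMM to 0.94 with library totals alone, and labelled gut from -0.23 to -0.29.

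Lists of genes for 18 pathways and cell types were fixed beforehand. Their direction was tested with limma 3.58.1 (camera with a preset correlation of 0.01, then estimated) for lists with at least 3 tested genes, on the tested regions of each gene summed, without and with the replicate block, and against 10000 random lists matched on mean count. The number of members with a tested region was set against 10000 random lists matched on gene length, a test added after the data were seen, as were the gene-end and mitochondrial shares. Named genes followed a rule: foxo in each tissue, the called regions with the largest fold changes, the 5 higher and 5 lower regions with the smallest adjusted p, called members of the lists, and genes called in both tissues. Only the first and the third part named genes, since 0 regions were called, and genes named as list members or as DESeq2 calls were chosen after their values were seen.

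The numbers of the gut replicates were taken to pair the samples by the bound set, which does not establish pairing. The deviations of same-numbered control and switched libraries from their group means correlated at 0.299, 0.218 and 0.113, each over the 0.1 set as the bound. Control replicate 3 correlated higher, at 0.128, with switched replicate 2. Its counts did so too (Spearman 0.602, against 0.536 with switched replicate 3). Both libraries numbered 1 were shallow, and shared shallowness cannot be told from pairing here. The pairing comes from the data, as the labels do not say what a number shares. With the replicate block, 0 regions labelled gut were called, as without it.

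The tests were tried on simulated counts drawn with the real means, library sizes and dispersion, with 200 regions changed by 4-, 16-, 64- or 256-fold, and every region called among the changed ones had the right direction. At 0.1 of the dispersion, the test called 86% of regions changed 4-fold in the table labelled fat body and 80% in the table labelled gut. Alternatives were thresholds of 0.01 and 0.1, a minimum change of 1 in log2, no filter or the regions of lowest mean count left out, genes as units, DESeq2 size factors, DESeq2, the replicate block and leaving out each library. Added after seeing the data were nuclear regions or chromosome arms alone, nuclear reads thinned to 1 depth, no scaling factors, and the gut without both libraries numbered 1. Figures were drawn with matplotlib 3.10.9.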

Results

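The chromatin accessibility of adult female Drosophila melanogaster was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. The flies carried the S106 driver and UAS-foxo, so that the steroid RU486 in the food induces foxo, the forkhead transcription factor that acts downstream of insulin signalling. Per the labels, induced flies ate 200 µM RU486 for 21 days and control food for the next 7 days, and uninduced flies served as controls. Fat body and gut were dissected, with 3 control and 3 switched libraries for each tissue. The comparison of switched with control flies asks whether a past period of foxo induction left a trace in chromatin after it had ended. Only switched flies ate RU486, and no group ate it without UAS-foxo. An effect of the drug itself can therefore not be told apart from the induction. The read counts were deposited for 3447 regions in the table labelled fat body and 2906 regions in the table labelled gut. Several gene lists leaned against the tissue labels, though for tested regions no list differed between the tables after adjustment. The libraries are therefore called labelled fat body and labelled gut throughout.

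Mitochondrial DNA held most counts in all 12 libraries, in regions at genes such as COX1, CYTB, ATP6 and ND4, which encode subunits of the respiratory chain and of the ATP synthase. In the libraries labelled fat body the mitochondrial share was 87.1% ± 2.41 (SD, n = 3) in control flies and 78.6% ± 4.34 (SD, n = 3) in switched flies. The difference of -8.53 percentage points separated all 3 switched from all 3 control libraries, and its exact two-sided permutation p of 0.1 is the smallest that 3 against 3 libraries can give. In the libraries labelled gut the share was 77.3% ± 7.88 (SD, n = 3) in control and 81.9% ± 5.13 (SD, n = 3) in switched flies (exact two-sided permutation p = 0.5). The difference between these differences was -13.1 percentage points, with an exact permutation p of 0.05, which is not below 0.05. Group labels were permuted within each tissue, so this p is set against no effect in either tissue and not against equal effects in both. At single regions of the table labelled fat body, ND4 had a log2 fold change of -0.86 ± 0.31 (SE) and COX2 of -0.79 ± 0.29, with edgeR adjusted p-values of 0.608 and 0.621. Neither passed the test.

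**Figure D1:**
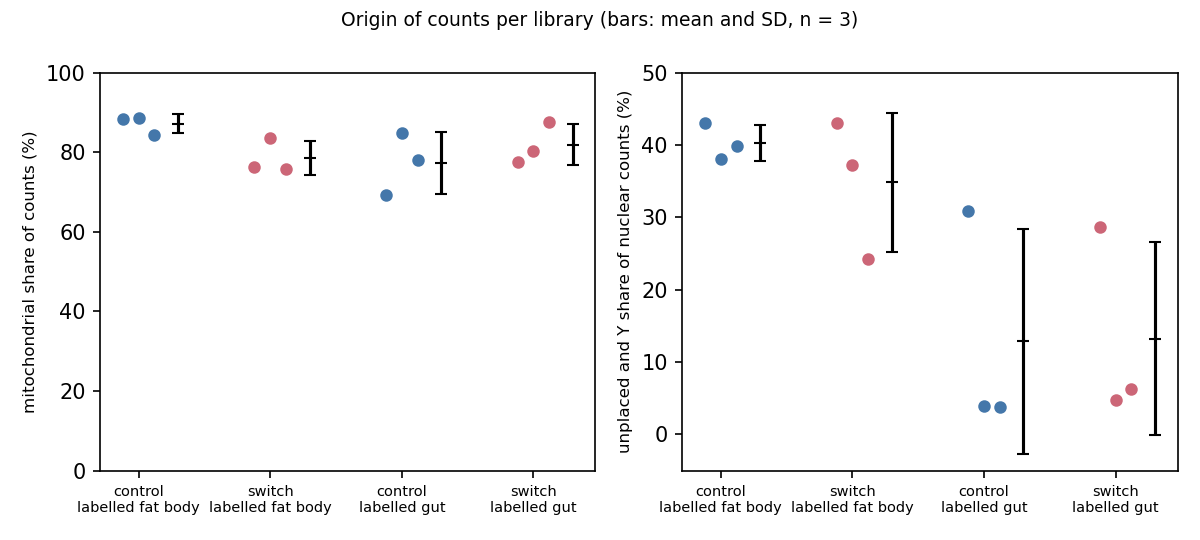
Share of counts in mitochondrial regions (left, percent of all counts) and share of nuclear counts on unplaced scaffolds and the Y chromosome (right, percent) for each library, with the mean and SD of each group of 3. The control libraries labelled fat body have 84.4% to 88.6% mitochondrial counts and the switched ones 75.8% to 83.6%, and on the right the libraries numbered 1 of the gut set stand at 30.8% and 28.7%.

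Total counts in the libraries labelled fat body were 1186153, 1136557 and 1053117 in control replicates 1 to 3 and 970698, 977245 and 811020 in switched replicates 1 to 3. In the libraries labelled gut they were 111244, 654180 and 519099 in control and 99191, 709659 and 577977 in switched flies. Both gut libraries numbered 1 were therefore shallow, and regions on unplaced scaffolds and the Y chromosome held 30.8% and 28.7% of their nuclear counts, against 3.77% to 6.32% in the other 4. With so many counts, the 95% Clopper-Pearson interval of a mitochondrial share is narrow, 88.4% to 88.5% in control replicate 1 labelled fat body and 68.9% to 69.4% in control replicate 1 labelled gut. These intervals cover counting error only, since amplified reads are not independent molecules.

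Genes of lipid storage and of the fat body stood out among the regions of the table labelled gut. Of 25 lipid genes, 15 had a tested region there, among them FASN1, a fatty acid synthase, Lsd-1, a perilipin of lipid droplets, bmm, the adipose triglyceride lipase, and apolpp, the precursor of the main lipoprotein. Only Acsl of this list had one in the table labelled fat body. The yolk protein genes Yp1 and Yp3 were 2 of 7 fat body markers with a region in the table labelled gut, against 3 (Lsp1beta, Lsp2 and srp) in the other table. Digestive enzyme genes lay the other way: alphaTry, Jon99Cii, Jon99Ciii, Jon99Fi, Mal-A2 and Mal-A7, which encode proteases and maltases of the gut lumen, had regions in the table labelled fat body, and only Mal-A5 in the table labelled gut. The gut transcription factor gene GATAe, Ptx1 and alphaTry were the 3 gut identity markers with a region in the table labelled fat body, and 0 of that list had one in the table labelled gut. Since alphaTry stands in both lists, the digestive and gut identity lists are not independent.

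Each list was set against 10000 random lists of protein-coding genes matched on gene length, with Benjamini-Hochberg adjustment over 18 lists and both tables. In the table labelled gut, lipid genes (15 against a random median of 4, adjusted p = 0.0036, the smallest that these random lists can give here), fat body markers (7 against 2, adjusted p = 0.0072), immune genes such as Rel and PGRP-SD (9 against 3, adjusted p = 0.0072) and oenocyte markers such as Cyp4g1 (5 against 1, adjusted p = 0.0189) had more members than chance. Gut identity markers were within chance in both tables (3 against 2, adjusted p = 0.847 labelled fat body, and 0 against 2, adjusted p = 0.368 labelled gut). Digestive genes exceeded chance in the table labelled fat body (6 against 1, adjusted p = 0.0048). FOXO and insulin genes, such as InR and Akt, exceeded it in both tables (8 against 3, adjusted p = 0.0175 labelled fat body, and 12 against 4, adjusted p = 0.0072 labelled gut). In the table labelled fat body that was lost with all regions (adjusted p = 0.0693), with regions overlapping the gene itself (0.205) and in control libraries alone (0.953). Hormone receptor and ecdysone genes such as EcR and Eip75B did so in the table labelled gut (12 against 4, adjusted p = 0.0036) and missed it in the other (9 against 4, adjusted p = 0.059, and 0.036 with regions overlapping the gene itself). In control libraries alone the calls of digestive genes (adjusted p = 0.103 labelled fat body), oenocyte markers (0.305), FOXO and insulin genes and hormone receptor and ecdysone genes (0.125 each, labelled gut) were lost, while those of lipid genes, fat body markers and immune genes held (0.0072, 0.0288 and 0.0432). For the difference between the tables itself, the exact p was 0.00344 for lipid genes and 0.00959 for digestive genes, and both missed the threshold after adjustment over 18 lists (0.0619 and 0.0864). With all regions in place of the tested ones both adjusted p-values were 0.02, with regions overlapping the gene itself 0.0236 and in control libraries alone 0.387, and with reads in all 6 libraries they were 0.488 and 1. Fat body markers lay near the share over all genes in the same exact test on tested regions (p = 0.721). Gut identity markers had an exact p of 0.0444 (0.160 adjusted), the same as muscle and neuronal markers. Restricting the regions to those with reads in all 6 libraries left 0 lists above chance in either table.

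**Figure D2:**
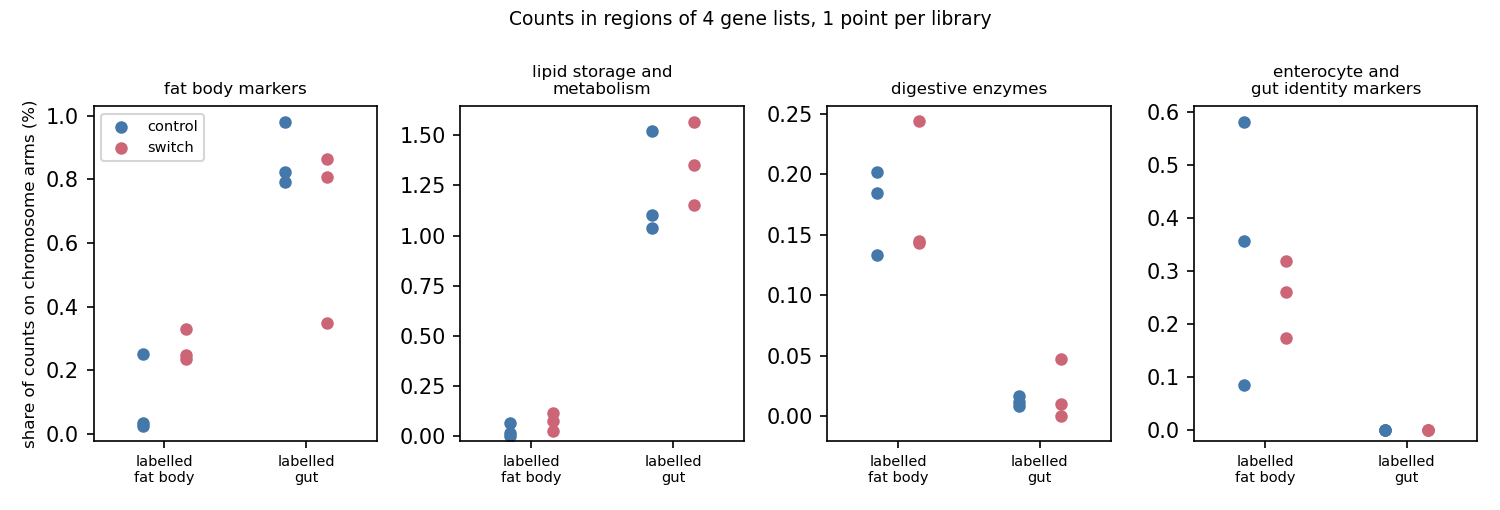
Share of the counts on chromosome arms (percent) that fell in regions of 4 gene lists fixed beforehand, with 1 point per library, control in blue and switched in red. Fat body markers take 0.348% to 0.981% of counts in the libraries labelled gut and 0.0252% to 0.330% in those labelled fat body, while digestive enzymes take 0% to 0.0477% and 0.133% to 0.244%.

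The regions of both tables also differed in where they lay. Of 2292 regions on chromosome arms in the table labelled gut, 44.5% (95% Clopper-Pearson interval 42.5% to 46.6%) had their midpoint within 500 bp of an end of a protein-coding gene, against 14% (12.5% to 15.5%) of 2028 regions in the table labelled fat body (Fisher's exact test, two-sided p = 1.22e-110). Regions of the table labelled gut moved by 5 or 10 kb fell at gene ends in 18.9% to 21.6% of cases, and those of the table labelled fat body in 12.4% to 13%. Among regions with reads in all 6 libraries the shares were 45.1% and 21.4%. Regions on unplaced scaffolds numbered 1353 in the table labelled fat body and 580 in the table labelled gut. The median region was 116 bp long in the former and 148.5 bp in the latter.

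**Figure D3:**
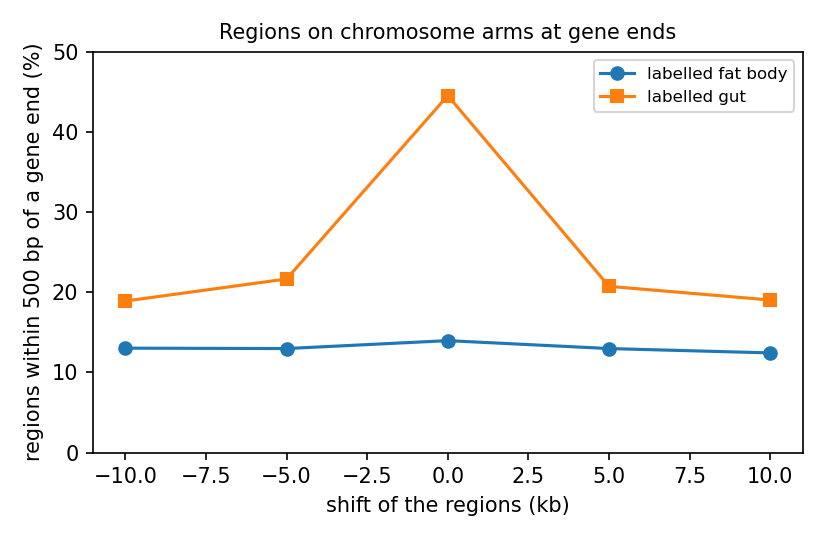
Share of regions on chromosome arms within 500 bp of a gene end (percent) at their deposited position and after moving them by 5 or 10 kb in either direction. The table labelled gut has 44.5% at its deposited position and at most 21.6% after a move, and the table labelled fat body 14% and at most 13%.

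RU486 induces foxo through UAS-foxo, so counts at the native foxo gene, in either table, are no check on the induction. In the libraries labelled fat body, this native gene had 1 tested region 51 bp outside it (3R, 14056777 to 14056894). The region had 64, 70 and 0 counts in control and 88, 104 and 358 in switched replicates. Its log2 fold change was 1.45 ± 1.48 (SE), with an edgeR adjusted p of 0.984. That value rested on single libraries and on scaling: it was 0.67 without switched replicate 3, 0.89 without control replicate 3 and 2.47 with library totals alone. No region passed the test: edgeR's quasi-likelihood test called 0 of 1674 tested regions at an adjusted p under 0.05, and the smallest adjusted p was 0.189. At an unadjusted p under 0.05 it gave 65 regions higher and 15 lower in switched flies, 80 in all. By chance 83.7 of 1674 would arise at that p, and the other divisions of the 6 libraries gave 14 to 32. These counts moved with the libraries used: without switched replicate 1, 2 or 3 they were 63 against 52, 72 against 52 and 87 against 48, with more lower regions and about as many or more higher ones, and without control replicate 1, 2 or 3 they were 147 against 16, 133 against 20 and 133 against 30. DESeq2 called 79 regions, 66 higher and 13 lower, and edgeR without a filter on low counts called 14 higher and 5 lower, so whether any region was called rested on the tool and, within edgeR, on the filter. Without each control library in turn DESeq2 called 138, 144 and 136 regions, and without each switched library 66, 65 and 71.

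The regions with the smallest p-values were read in the libraries of 1 group and nearly absent from the other. A region inside Mob2, which encodes a kinase activator (3L, 11531460 to 11531602), had 0 counts in each control library and 77, 274 and 303 in the switched ones, which is at least 169.8-fold higher with 3 counts over the control group as the floor. Regions at Taf1, a subunit of the general transcription factor TFIID (3R, 6647548 to 6647629; at least 129-fold), and 60 bp outside Ppa (2R, 22689047 to 22689119; at least 112-fold) were likewise read in switched libraries alone. A region in lovit (3L, 25443265 to 25443334) had 1, 0 and 0 counts against 67, 240 and 157, and one in lola, a transcription factor gene (2R, 10530735 to 10530830), 1, 0 and 0 against 111, 85 and 238. In the other direction, regions in CG45263 (3R, 8460610 to 8460680; at least 162-fold lower), in SA1, a cohesin subunit gene (2L, 6950905 to 6950975; at least 134-fold lower), and in CG45075 (2L, 6094614 to 6094684; at least 32.5-fold lower) had counts in each control library and 0 in the switched ones. So did 2 regions of the X chromosome without a gene within 1000 bp, at 22083954 to 22084216 (at least 130.1-fold lower) and at 8673829 to 8673950 (at least 128-fold lower). The lower bounds of these folds cover counting error only, so with the spread between libraries the true folds may be smaller. The edgeR adjusted p of all 10 regions was 0.189, while DESeq2 gave them adjusted p-values from 9.63e-06 (Taf1 and CG45263) to 0.0117 (CG45075).

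The 79 regions called by DESeq2 lay at 55 genes or at no gene, and 41 of the 66 higher ones had 0 counts in all 3 control libraries. The following genes among them were chosen after their values were seen. A region in Eip78C, an ecdysone-induced nuclear receptor gene, had 0 counts in control and 65, 77 and 206 in switched libraries. Summed over its tested regions, Eip78C had 2, 33 and 0 counts in control and 246, 207 and 272 in switched libraries. A region in Nmnat, whose product makes NAD, had 143, 48 and 144 in switched libraries and 0 in control. Mdr65, a transporter of the blood-brain barrier, had 0, 3 and 0 against 295, 60 and 60 counts, with a log2 fold change of 6.45 ± 1.91 (SE). A region in the stress-responsive transcription factor gene Atf3 had 0, 0 and 1 against 188, 53 and 50. Other regions had counts in every library, such as one in sls, the titin-like muscle protein gene, at 9.41 ± 9.82 CPM in control and 180.3 ± 72 in switched flies (SD, n = 3), and one in zpg, a germline innexin gene, at 9.69 ± 12.6 and 142.9 ± 27.7. The median called region was 73 bp long, against 109.5 bp for all tested regions.

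None of the gene lists passed the test as a whole in the libraries labelled fat body. The FOXO and insulin list had 8 tested genes with 0 called by edgeR, 5 above 0 and 3 below. With the regions of each gene summed, Thor, the translation inhibitor 4E-BP and a direct FOXO target, had a log2 fold change of 1.92 ± 1.82 (SE), Akt 1.37 ± 1.61 and InR, the insulin receptor gene, -0.48 ± 0.77. The unfolded protein response was represented by Xbp1 alone, at 2.92 ± 1.99. Of 4 chromatin remodeller genes 2 were above 0, mor at 1.99 ± 1.77 and dom at 1.04 ± 1.06, and 2 below, kis at -0.19 ± 1.18 and e(y)3 near 0. Of 9 hormone receptor and ecdysone genes 7 were above 0, Eip78C highest. The median of that list, 0.44, lay below the 0.64 of all genes. Of 3 haemocyte markers all 3 were above 0, such as eater at 3.73 ± 1.80, a phagocytic receptor gene. Every switched library exceeded every control library in the share of counts on chromosome arms at haemocyte markers (0.104% to 0.120% against 0.00498% to 0.0449%). Muscle markers did likewise (0.336% to 0.483% against 0.214% to 0.254%). At immune and heat shock genes every switched library lay below. The heat shock list had 1 tested gene, and its counts were 158, 132 and 197 in control and 69, 115 and 215 in switched replicates. Switched replicate 3 thus lay below only through its larger total on chromosome arms (148529, against 77983 to 99026 in control). These shares were not tested. The lists named are those, of all lists fixed beforehand, whose shares separated the groups. With 3 against 3 libraries some of so many lists can separate by chance. All 3 immune genes were below 0, such as imd at -0.88 ± 0.86. Digestive genes split into 3 above and 3 below 0, muscle markers into 3 and 1, and gut identity, fat body and neuronal markers into 2 and 1 each. Detoxification genes stood 2 above and 1 below, and Mdr65 was the only gene called when sums were adjusted over the list alone, against 0 over all genes tested. At single regions adjusted that way, the hormone receptor and muscle lists had 1 call each as well. These lists had camera adjusted p-values of at least 0.825, and at least 0.870 with an estimated correlation. Lipid, heat shock, stem cell and enteroendocrine, ovary and unfolded protein response lists had 1 tested gene each here, oenocyte markers 2 and Malpighian tubule markers 0. Digestive, gut identity and neuronal lists had a median above 0 and a camera direction below other genes, whose median log2 fold change was 0.64, and for gut identity markers the mean was -0.09. All these values come from libraries whose mitochondrial share was 87.1% in control and 78.6% in switched flies.

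In the libraries labelled gut, a region inside foxo (3R, 14062292 to 14062415) had 9, 53 and 16 counts in control and 0, 26 and 47 in switched replicates, a log2 fold change of -0.23 ± 1.63 (SE) with an edgeR adjusted p near 1, and its sign changed without control replicate 2 or without switched replicate 1 or 2. No region passed the test here either: edgeR called 0 of 1944 regions, with a smallest adjusted p of 0.855, DESeq2 called 0, and edgeR without a filter on low counts called 0. At an unadjusted p under 0.05, edgeR gave 8 regions higher and 23 lower in switched flies, 31 in all. By chance 97.2 of 1944 would arise at that p, and the other divisions of the 6 libraries gave 6 to 115. Single libraries moved these counts: they were 26 and 36, 42 and 35, and 12 and 27 without control replicate 1, 2 or 3, and 18 and 66, 4 and 157, and 10 and 84 without switched replicate 1, 2 or 3. Leaving out both shallow libraries numbered 1, which was chosen after seeing the data, left the edgeR count at 0, while DESeq2 then called 2 regions, both lower.

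The regions with the smallest p-values in the libraries labelled gut held few counts. Higher in switched flies were regions in Osi7, with 0 counts in control and 8, 18 and 11 in switched libraries (3R, 6249804 to 6249951; at least 11.1-fold), in CG11857 (3R, 25258940 to 25259048; at least 14.2-fold), in Con, a cell adhesion gene (3L, 4969213 to 4969320; at least 19-fold), and in ken, a transcriptional repressor gene (2R, 23872280 to 23872451), with 0, 1 and 0 against 6, 75 and 13. A region at an end of dup, the Cdt1 replication licensing gene (2R, 15380871 to 15381102), had 11.8 ± 5.89 CPM in control and 159.3 ± 60.1 in switched flies (SD, n = 3). Lower were regions in CG40228 (3L, 27083859 to 27083959; at least 44.6-fold), in Nurf-38, a subunit of the NURF remodelling complex (2R, 24560773 to 24560928; at least 33.2-fold), in CG33144 (2R, 10755587 to 10755668; at least 13.3-fold), in CG7987 (3R, 14575425 to 14575563; at least 15.9-fold), and at 2R, 4655824 to 4655969, without a gene within 1000 bp (at least 13.7-fold). Each of these last 5 had 0 counts in all 3 switched libraries. Adjusted p-values by edgeR ran from 0.855 to nearly 1.

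No list of genes passed the test as a whole in the libraries labelled gut. Of 12 FOXO and insulin genes 6 were above and 6 below 0, with Cat, the catalase gene, at 2.29 ± 1.87 (SE, regions of each gene summed), Akt at 1.87 ± 1.73 and Pi3K21B, a regulatory subunit of phosphoinositide 3-kinase, at -2.28 ± 1.44 in log2. Lipid genes split into 8 above and 7 below 0, with bmm at 1.86 ± 1.71 and Hnf4, a nuclear receptor of lipid use, at -0.60 ± 0.74. Fat body markers were above 0 in 2 and below in 5 of 7, with Yp1 at -0.88 ± 0.76. Of the 3 genes of the unfolded protein response, Calr stood at -0.87 ± 1.31, Herp at -0.81 ± 1.34 and Ire1 near 0. Among 5 remodeller genes 2 were above and 3 below 0, with E(bx), the largest NURF subunit gene, at -3.34 ± 1.83 and Acf at 2.48 ± 1.87. Immune genes stood 6 above and 3 below 0, detoxification genes 1 and 4, hormone receptor and ecdysone genes 5 and 7, oenocyte markers 3 and 2, and haemocyte markers 0 and 3. These counts are against 0, while the median log2 fold change over all genes was -0.21 and 40.9% of tested regions were above 0. The hormone receptor list had a median of -0.13, a mean of 0.36 and a camera direction above other genes. In this table too, camera adjusted p-values were at least 0.825, and at least 0.870 with an estimated correlation. With the replicate number as a block, they were at least 0.842 and 0.897. Digestive, heat shock, muscle, stem cell and enteroendocrine, ovary and Malpighian tubule lists had 1 tested gene each here, and gut identity and neuronal markers had 0.

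Setting both tables side by side asks whether the response to the past induction differed between the tissues. Merging overlapping regions gave 857 regions, of which 615 were tested, and the edgeR interaction test called 0 of them (27 at an unadjusted p under 0.05, and no other tool was run). The smallest interaction p belonged to lola, whose merged region (2R, 10530669 to 10530830) had 1, 0 and 0 against 111, 85 and 238 counts labelled fat body and 11, 22 and 11 against 0, 18 and 55 labelled gut, with an adjusted p near 1. Of 283 genes tested in both tables, 0 were called in both and 0 had an unadjusted p under 0.05 in the same direction in both, where 0.0318 higher in both would arise by chance. Across these genes, which are not independent replicates, the log2 fold changes had a Spearman correlation of -0.025 and a Pearson correlation of -0.0456. Directions by tissue follow the labels, which several gene lists leaned against. The differences between the tables for lipid and digestive genes passed adjustment under some choices of regions and missed it under others. Those for fat body and gut identity markers passed it under none.

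With 0 regions called by edgeR in either table, the location of changed regions has no value under that test. Of the 79 regions called by DESeq2 in the table labelled fat body, 70 lay on chromosome arms. Of these 18.6% had their midpoint within 500 bp of a gene end, as had 18.6% of 1314 other regions with a DESeq2 adjusted p (Fisher's exact test, adjusted p = 1), and the shares were 21.7% of 60 higher and 0% of 10 lower ones (adjusted p = 0.379). This comparison was added after the data were seen. Simulated counts with the spread of these libraries show what could be called when many regions change strongly at once, which eases the adjusted threshold. In the table labelled fat body, edgeR recovered 6% of regions changed 4-fold, 12% changed 16-fold and 68% changed 64-fold. Each share is of 50 regions among 1473 tested. In the table labelled gut the same sizes gave 0%, 10% and 66% of 50 each among 1244 tested. Changes of 4-fold were thus hardly detectable at this depth and spread. The shares at 64-fold may overstate what could be called in the real data. There, regions labelled fat body at Mob2 (at least 169.8-fold), CG45263 (at least 162-fold) and Taf1 (at least 129-fold) were not called. Their edgeR adjusted p was 0.189. They were picked by smallest p and their bounds cover counting error only, so their true folds may be smaller. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

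**Figure D4:**
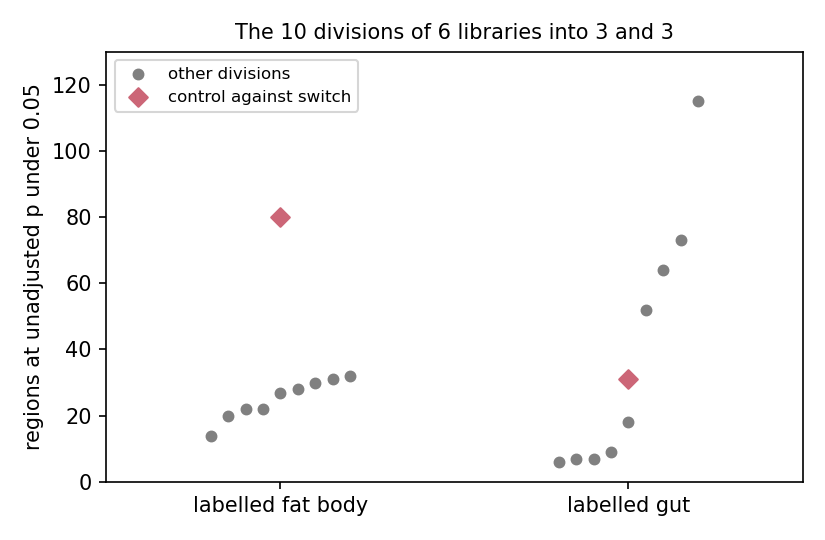
Number of regions at an unadjusted edgeR p under 0.05 for each of the 10 divisions of the 6 libraries of a table into 3 and 3, with control against switched as a diamond. In the table labelled fat body the real division gives 80 regions and the others 14 to 32, and in the table labelled gut it gives 31 and the others 6 to 115. At that p, 83.7 and 97.2 regions would arise by chance.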

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

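The alternatives on nuclear regions, chromosome arms, thinning, scaling and both gut libraries numbered 1, and all those on lists above chance, gene ends and the mitochondrial share, were chosen after seeing the data. The count of changed regions labelled fat body was 0 under edgeR except without a filter on low counts, where it was 19, and it was 79 with DESeq2, which differs in filter, scaling and test at once. The gut count was 0 under every alternative except DESeq2 without both libraries numbered 1, where it was 2. Leaving out each library in turn gave 0 regions with edgeR each time in either table, and 65 to 144 with DESeq2 labelled fat body. With the replicate block, 0 regions were called labelled fat body and 0 labelled gut, 0 regions in the interaction test, 0 genes in both tissues and 0 list directions. The fat body numbers share only a number: same-numbered libraries correlated at 0.00134, -0.0276 and -0.0661, and not every library correlated best with its own number. The last point held in the gut too, where control replicate 3 correlated at 0.128 with switched replicate 2 and at 0.113 with its own number. The interaction, the genes changed in both tissues and the list directions stayed at 0 under the alternatives run for each. Motif alternatives were not run, for lack of a genome. Gene-end windows for changed regions had no edgeR calls to use; of the DESeq2 calls 18.6% lay within 500 bp, 4.29% within 200 bp and 30% within 1000 bp of a gene end. Lists above chance labelled fat body fell from 2 to 1 with all regions and to 0 in control libraries alone or with reads in all 6 libraries; labelled gut they fell from 6 to 3 in control libraries alone and to 0 with reads in all 6, where fewer regions remain. The gap in gene-end share of -30.5 points was -26.6 with a window of 200 bp and -23.8 for regions with reads in all 6 libraries. The mitochondrial difference labelled fat body ranged from -11 to -7.14 without each library. For foxo labelled fat body the value of 1.45 ranged from 0.67 to 1.94 without each library and was 2.47 with library totals alone. For foxo labelled gut the sign turned positive without control replicate 2 (0.38), without switch replicate 1 (0.36) or 2 (0.03), within a range from -1.59 to 0.38 without each library, and without both libraries numbered 1 (0.18 with edgeR and 0.18 with DESeq2). Of 22 named regions, 11 passed the threshold under at least 1 alternative, and 346 of 351 alternative values kept their sign. The 5 others were the positive values of foxo labelled gut given above. Apart from foxo, the regions were picked by smallest p in these same data. Most of them had 0 counts in all libraries of 1 group, so their sign could hardly change, and its stability is no sign of robustness. The spread between libraries, with a dispersion of 1.40 and 1.38, limits what could be called, and in the shallow gut libraries so does depth: thinning all gut libraries to 22164 nuclear reads left 559 tested regions.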

Other observations

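The tests on tissue markers, amplified fragments, the spread of the thinned ratio, the simulated shared response, read stacks, the build and the splits of region and list counts were chosen only after the results were seen. Beyond the comparisons, in the libraries labelled gut, regions at Yp1, a yolk protein gene, had a control mean of 313.4 ± 87.6 CPM (SD, n = 3), those at Adh, alcohol dehydrogenase, 579 ± 443, at Cyp4g1, the hydrocarbon synthase of oenocytes, 408 ± 309, and at Obp99c 383 ± 91.2, for the region with the smallest p of each gene. These genes were chosen after their values were seen. Haemocyte markers had 3 genes in each table, Col4a1, eater and lz labelled fat body and Col4a1, crq and vkg labelled gut. Muscle markers had 4 labelled fat body (Mef2, Mlp84B, Prm and sls) and 1 labelled gut, and neuronal markers 3 (cac, Rdl and Sh) and 0. Heat shock genes were represented by Hsp70Ba and DnaJ-1, the stem cell and enteroendocrine list by E(spl)m3-HLH and CCHa2, the ovary list by Vm26Ab and Cp38, and the Malpighian tubule list by 0 genes and tsh.

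Lipid genes led in the table labelled gut and digestive genes in the table labelled fat body. Fat body markers had 7 genes with a region labelled gut and 3 labelled fat body, near the share over all genes (exact p = 0.721). A surplus of regions in the table labelled gut that is even over genes of like length is argued against by lipid genes. They exceeded random lists drawn in that same table (adjusted p = 0.0036). Digestive genes, which lay the other way, argue less so (exact p = 0.00959, 0.0864 after adjustment over 18 lists). An uneven surplus stays open: FOXO and insulin (12 against 4), hormone receptor (12 against 4) and immune genes (9 against 3) exceeded random lists there too. Exchanged tissue labels stay an untested hypothesis: the share of counts on chromosome arms separated the tables in that direction for all 4 lists, but these shares repeat which genes have regions, and for gut identity genes the share labelled gut was fixed at 0. Fat tissue carried along with a correctly labelled gut stays open, because the absence of gut identity genes from that table was within chance (adjusted p = 0.368). Of the 17 fat body markers, apolpp, FASN1, Desat1 and Mtp also stand among the lipid genes, so these lists are not independent, and regions exist in each table only where they were called.

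In the table labelled fat body, more regions were higher than lower in switched flies at an unadjusted p (65 against 15), with 63 against 52, 72 against 52 and 87 against 48 without switched replicate 1, 2 or 3 and 147 against 16, 133 against 20 and 133 against 30 without control replicate 1, 2 or 3. A larger yield of nuclear reads in the switched libraries is argued against as the whole cause only within the given regions. After nuclear reads were thinned to 1 depth 58 regions were higher and 12 lower. The ratio was 4.83 (3.67 to 7.25 over 20 further draws), against 6.89 for nuclear regions before thinning. Without switched replicate 1, 2 or 3 it was 1.19, 1.5 and 1.90 against 1.22, 1.8 and 1.86. Thinning cannot undo an effect of depth on which regions were called, so that stays open. The median count of regions on chromosome arms was 6, 3 and 4 in control replicates 1 to 3. In switched replicates 1 to 3 it was 35, 15 and 20. Amplified copies of few distinct fragments may give regions read in all libraries of 1 group and none of the other. The real split had 69 such regions and the highest other split 42, and it was the only 1 of 10 with as many, but 10 splits are too few for a share under 0.05. The induction and the RU486 in the food, which cannot be told apart here, stay among the open explanations, untested.

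Few regions of the table labelled fat body lay at gene ends. Regions read in few libraries are argued against as the whole cause. Those with reads in all 6 libraries had 21.4% at gene ends. The upper bound of that share, 24.9%, lay below the 40.8% lower bound of the table labelled gut. Stacks of reads stay open, since 1 read in a library was enough to count it. With reads in 1 library alone the share was 2.33%, and 8.04% in the table labelled gut. Coordinates of another build are argued against by 411 overlaps with the other table, against at most 17 after a move by 5 kb. Whether the gap comes from regions outside those shared with the other table stays open: shared regions had 23.6% at gene ends and the others 11.5%, but the 24.3% of their partners in the table labelled gut is set by the overlap itself and decides nothing. Unshared regions of the table labelled gut had 48.8%, and no biological explanation was tested.

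Divisions of the 6 libraries of a table into 3 and 3 are 10, too few for a share under 0.05. The region count labelled fat body was 0 and all 10 divisions had as many, with a highest other count of 0; labelled gut it was 0, all 10 had as many and the highest other count was 1. With DESeq2 the real division labelled fat body called 79 regions and the highest other 21, and it was the only 1 with as many. The lists called were 0 in both tables in all 10 divisions, with a highest other count of 0. For the interaction, all 100 drawn combinations called as many as the real 0, with a highest other of 0; any count matches a real 0, so this and the other counts of 0 say nothing about chance. In the table labelled gut the division of control replicate 1 and switch replicates 1 and 3 from the rest gave 115 regions at an unadjusted p under 0.05 against 31 for the real one, which points to a structure of the samples other than the induction; both libraries numbered 1 stand on the same side of it. Of the 4 divisions that part all 3 numbered pairs in this table, the real one gave 31 such regions and the others 6 or 7, while the 6 that keep a pair together gave 9 to 115.

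A common response of both tissues was tested through the correlation of log2 fold changes across the 283 genes tested in both tables. Of 100 combinations of splits, 65 gave a Spearman correlation as large in size as the real -0.025, and the highest other was 0.146. The bound set for that test was wrong as an exclusion of small responses: with a shared response of 0.25 (SD, log2) added across all genes, the correlation passed the bound in 16.2% of 99 combinations, against 81.8% with 0.5 and 100% with 1. The response was added to the finished log2 fold changes and not to the counts, where libraries with 0 counts would damp it. These shares may therefore be too high. A shared response that is smaller or limited to some of the genes stays open. A broad one with an SD of 1 in the fold changes themselves is not what these values show.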
